A study of Mus musculus with 37 samples.

How the data were processed

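Total RNA from mammary tissue of female BALB/c mice was hybridised to 37 Affymetrix arrays, 1 per sample. The deposited values were log2 expression values made with RMA, which corrects background, normalises between arrays and summarises probes, and with the oligo package, per the submitters' processing notes. Their versions were not given in the sources used here. The value table held 35556 probe sets with no missing value, from 0.817 to 13.8, and array medians lay between 5.04 and 5.25. No further normalisation was applied. Columns were matched to samples by the sample identifier that names them, and titles gave the groups. The precision of every comparison is limited by the number of arrays.

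Probe sets were named through the platform annotation supplied with the series. It listed 23099 probe sets, of which 21218 had 1 gene symbol and 1881 had several, and 12457 were not listed. Probe sets with several symbols or none were left out. Of the named probe sets, 21185 had a gene identifier in the RefSeq table, and 0 changed their symbol. Of the 18820 genes, 1386 had several probe sets, and the one with the highest mean over all arrays was used. Probe sets of the same gene often disagreed: the median correlation of the first 2 was 0.387, and 616 genes lay below 0.3. Genes were tested when their mean lay above the 30th percentile of all named genes (log2 4.04), which kept 13174.

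The labels gave 4 treatments at 3 times, which made 12 groups of 3 arrays, except the sham group of week 4 with 4. A single limma model with a mean for each of the 12 groups was fitted to all 37 arrays (lmFit and eBayes, default settings, 25 residual and 3.4 prior degrees of freedom). Contrasts set each irradiation against the sham arrays of the same week and against sham over the mean of the 3 weeks. Further contrasts set 30 cGy Si against 100 cGy gamma and against 10 cGy Si, and sham weeks against each other, and a moderated F test covered the 6 differences of an effect between weeks. All tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a call at an adjusted p under 0.05. Every adjusted p of a single gene comes from limma. Counts of genes at an unadjusted p under 0.05 are also given. If no gene changed, a share of about 0.05 of the 13174 genes tested would be expected there, and correlated genes can move this share.

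The contrasts, 38 gene lists, the filter, the rule for naming genes and the alternatives, apart from those listed as later additions, were chosen before the data were examined. Of 937 list entries, 846 matched a gene of the table and 784 passed the filter. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the arrays, adjusted over the lists of a contrast. A list's value is the mean log2 difference of its members. A list score of an array is the mean deviation of the members from their own means over the 37 arrays. Counts of called members are given over all genes tested and adjusted over the list alone.

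Genes were named by a fixed rule. For each contrast these were up to 10 called genes per direction with the largest difference. Where fewer than 10 genes were called, the 5 per direction with the smallest unadjusted p were added as values. For each list described, up to 4 members with the largest difference were named, and Cdkn1a, Mdm2, Ccng1, Phlda3 and Eda2r were followed in the irradiation contrasts. Predicted genes, small RNAs, pseudogenes and receptor segments were counted but passed over. Not every gene that the rule names is printed.

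The alternatives were no filter, a filter at the 50th percentile, the mean of a gene's probe sets, quantile normalization of the deposited values, eBayes with trend and robust settings, array weights, the replicate number as a block, a fit of only the groups of a contrast, 4 covariates for the mix of tissues, and leaving out each array in turn. The covariates were the mean levels of lymphocyte, skeletal muscle, epithelial and brown adipocyte genes. An exact permutation of list scores within weeks, fits without the 2 arrays least like the rest, and contrasts between weeks over all 4 treatments were added after the data had been seen.

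The gene test was tested on simulated data built from the real means and spreads of the 13174 genes, with 200 genes changed, in 5 runs. For 10 cGy Si against sham at week 1 it recovered 48.4% of genes changed 1.5-fold, 85.4% of those changed 2-fold and 98.8% of those changed 4-fold, with 5.72% false calls. For 30 cGy Si against sham over 3 weeks, 86.0% were recovered at 1.5-fold and 97.0% at 2-fold. For sham week 4 against week 1, 54.0% were recovered at 1.5-fold and 86.6% at 2-fold. In 20 simulated runs of the 10 cGy Si contrast at week 1, with the preset correlation, a list of 16 members shifted by 0.5 was called 20 times, with 1 call among 740 tests of other lists. With 200 genes changed, the adjusted threshold is looser than where few genes change, so recovery may be lower in contrasts with few changed genes. Genes were drawn independently in all these simulations. They cannot show how many false calls the preset correlation gives where genes are correlated, as in the real arrays. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.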

Results

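Gene expression was measured in intact inguinal mammary glands of mice that had received sham treatment, 100 cGy of gamma rays, which ionize sparsely, or 30 or 10 cGy of silicon ions (Si, 350 MeV/amu), which ionize densely along their tracks. The mice were exposed at 10 weeks of age, and glands were collected 1, 4 and 12 weeks later. The opposite inguinal gland had been cleared earlier. Glands of week 1 were collected at the irradiation facility, and those of weeks 4 and 12 after the mice had been moved back. Each treatment had 3 arrays per week, except sham at week 4 with 4, and the groups answer how the gland responds to radiation of either kind over time. The labels name replicates as separate samples and say no more of them, so p-values measure the spread between these samples, which may be technical.

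Correlations between arrays ranged from 0.949 to 0.994 with a median of 0.984. Sham week 1 replicate 3 and sham week 4 replicate 1 were least like the others, with median correlations of 0.970 and 0.971. Differences below are log2 differences ± SE from the limma model. Lists were called 192 times over the 16 planned comparisons with the preset correlation and 3 times with an estimated one. Those 3 were the heat shock, glucocorticoid response and endoplasmic reticulum stress lists after 10 cGy Si at week 1. In camera, every other list called in those 16 comparisons was called only with the preset correlation. An exact permutation of list scores, added later, is given under other observations. Differences of an effect between weeks are given with an estimated correlation.

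At 1 week after 100 cGy gamma, 3 genes rose against sham (3 arrays against 3) and 0 fell. Psrc1, a microtubule-binding p53 target, rose by 1.28 ± 0.23, a 2.42-fold change (adjusted p = 0.0251). Ace, the angiotensin-converting enzyme, rose by 0.70 ± 0.13 and Fam102b by 0.71 ± 0.13, with the same adjusted p. The p53 targets, transcripts of the DNA damage response, averaged 0.26 higher, and 24 of 28 members lay above 0. Of these, 1 was called over all genes and 4 adjusted over the list alone. Cdkn1a, the cell-cycle inhibitor p21, differed by 0.99 ± 0.31 (adjusted p = 0.374) and the receptor gene Eda2r by 0.84 ± 0.21 (adjusted p = 0.285). Values were smaller for Ccng1 (0.33 ± 0.15), Mdm2 (0.17 ± 0.11) and Phlda3 (0.004 ± 0.30). The list had an adjusted p of 0.000435, and an adjusted p of 0.273 with an estimated correlation. With the filter at the 50th percentile it averaged 0.173 and was no longer called (adjusted p = 0.0617).

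Other groups of genes moved in the same week 1 gamma comparison. The 11 mast cell genes averaged 0.38 higher (adjusted p = 6.98e-06, adjusted p = 0.291 with an estimated correlation), with 0 called over all genes and 7 higher and 1 lower adjusted over the list alone. Cpa3, the mast cell carboxypeptidase, differed by 1.18 ± 0.30 and Kit by −0.63 ± 0.28. The mast cell mean was 0.188 without sham replicate 3 and 0.230 without gamma replicate 2. Fibroblast genes averaged 0.29 higher, 18 of 21 above 0 (adjusted p = 4.54e-06, adjusted p = 0.404 with an estimated correlation). Ribosomal protein genes averaged −0.18, with 1 of 24 above 0 (adjusted p = 4.54e-06, adjusted p = 0.482 with an estimated correlation). T and NK cell genes averaged −0.87 with 0 of 22 above 0 (adjusted p = 2.12e-05, adjusted p = 0.731 with an estimated correlation). That value rested on sham replicate 3, without which it was −0.0945 (adjusted p = 0.709), while without sham replicate 2 it was −1.51.

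The 3 calls of this comparison came from 1030 genes at an unadjusted p under 0.05. Leaving out gamma replicate 2, sham replicate 2 or sham replicate 3 left 0 calls, leaving out gamma replicate 3 left 1 and leaving out sham replicate 1 gave 5. A fit of only these 6 arrays called 0 genes. Psrc1 was 0.858 without gamma replicate 2, 1.27 without sham replicate 2 and 1.20 without sham replicate 3, and was called in none of these. Fam102b lost its call without gamma replicate 2 (0.678), gamma replicate 3 (0.596), sham replicate 2 (0.741) or sham replicate 3 (0.615). Ace kept its call only without sham replicate 1, and ranged from 0.607 without sham replicate 3 to 0.742 without sham replicate 2, with 0.736, 0.692 and 0.681 without gamma replicates 1, 2 and 3.

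At 4 weeks after gamma, limma called 0 genes (3 arrays against 4), and 732 had an unadjusted p under 0.05. The smallest p-values belonged to Mamdc4 (0.64 ± 0.13), the matrix protein gene Tinagl1 (0.54 ± 0.12), the receptor kinase gene Ephb4 (0.44 ± 0.097) and Trp53bp1, a DNA break response gene (0.45 ± 0.10), all with an adjusted p of 0.36. Lowest by the same rule were Foxq1 (−0.53 ± 0.15) and Enpep (−0.81 ± 0.25), both with an adjusted p of 0.798. Cdkn1a differed by 0.20 ± 0.29 (adjusted p = 0.883) and Ccng1 by −0.35 ± 0.14 (adjusted p = 0.798).

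Oxidative phosphorylation genes, which encode the respiratory chain, averaged −0.26 in that comparison with 0 members above 0 (adjusted p = 1.49e-12, adjusted p = 0.88 with an estimated correlation). Cytochrome c (Cycs) differed by −0.68 ± 0.29. Without sham replicate 1 the mean was −0.113, and with covariates for the mix of tissues it was −0.0423, where the call was lost (adjusted p = 0.142). Brown adipocyte genes averaged −0.37 (adjusted p = 4.42e-05, adjusted p = 0.88 with an estimated correlation), and −0.195 without sham replicate 1, where the call was lost (adjusted p = 0.0845). Skeletal muscle genes averaged −1.31 (adjusted p = 3.32e-07, adjusted p = 0.89 with an estimated correlation). They were at −0.756 without gamma replicate 1, −0.670 without sham replicate 3 and −2.23 without sham replicate 1. Genes of basal epithelium averaged 0.39 higher (adjusted p = 6.58e-06, adjusted p = 0.89 with an estimated correlation), led by the keratin gene Krt17 (0.79 ± 0.38). Their mean was 0.172 without sham replicate 1, and 0.201 without gamma replicate 2, where the call was lost (adjusted p = 0.125).

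At 12 weeks after gamma, limma called 0 genes (3 arrays against 3), with 372 at an unadjusted p under 0.05 and 1 call without gamma replicate 1. Per1, a core gene of the circadian clock, differed by −1.03 ± 0.24, and Nr2f1 by −0.42 ± 0.10 (both adjusted p = 0.873). Tsc22d3, a glucocorticoid-induced transcript, differed by −0.62 ± 0.16 (adjusted p = 1). Glucocorticoid response genes averaged −0.25, with 5 of 21 members above 0, 0 called over all genes and 2 lower adjusted over the list alone (adjusted p = 6.06e-06, adjusted p = 0.721 with an estimated correlation). The mean was −0.151 without gamma replicate 2. Immediate early genes averaged −0.23, with 3 of 22 above 0 (adjusted p = 0.000774, adjusted p = 0.934 with an estimated correlation). Skeletal muscle genes averaged 1.39 higher in all 27 members (adjusted p = 2.29e-07, adjusted p = 0.934 with an estimated correlation), but 0.169 without gamma replicate 2 (adjusted p = 0.878) and 2.27 without gamma replicate 1. Cdkn1a differed by −0.14 ± 0.31 and Phlda3 by 0.38 ± 0.30, both with an adjusted p of 1.

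Over the 3 weeks together (9 gamma against 10 sham arrays), limma called 0 genes, with 706 at an unadjusted p under 0.05 and 1 call without gamma week 4 replicate 1. Slc9a3r2, a scaffold protein of ion exchangers, differed by 0.40 ± 0.077 and the nuclear receptor gene Nr2f1 by −0.29 ± 0.056, both with an adjusted p of 0.129. Tinagl1 differed by 0.34 ± 0.072 (adjusted p = 0.222), Ccnd3, a cyclin, by 0.27 ± 0.061 and Foxq1 by −0.39 ± 0.088 (both adjusted p = 0.325). Cdkn1a was at 0.35 ± 0.18 (adjusted p = 0.928) and Eda2r at 0.36 ± 0.12 (adjusted p = 0.801). Ribosomal protein genes averaged −0.099, with 1 of 24 above 0 (adjusted p = 1e-07, adjusted p = 0.864 with an estimated correlation), and −0.0510 without sham week 12 replicate 1.

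At 1 week after 30 cGy Si, 3 genes rose against sham (3 arrays against 3) and 0 fell. Gsta3, a glutathione S-transferase, rose by 1.14 ± 0.20, a 2.20-fold change. Morc4 rose by 0.75 ± 0.13, and Clmp, an adhesion molecule of epithelial junctions, by 0.54 ± 0.096, all with an adjusted p of 0.0215. The carbonic anhydrase gene Car13 differed by 1.02 ± 0.20 and Fam110c by 1.26 ± 0.25 (both adjusted p = 0.0557). Ace differed by 0.61 ± 0.13 and Rarres1 by 0.84 ± 0.18, with an adjusted p of 0.0756 that Phxr4 (−0.88 ± 0.18) and Baz2a (−0.46) shared. Cdkn1a differed by 1.15 ± 0.31 (adjusted p = 0.261), Eda2r by 0.39 ± 0.21 and Mdm2 by −0.009 ± 0.11. At an unadjusted p under 0.05 there were 1587 genes. A fit of only these 6 arrays, or covariates for the mix of tissues, left 0 calls. Without Si replicate 1, Si replicate 2 or sham replicate 2, 0 genes were called, and Gsta3 was then at 1.07, 1.11 and 1.09. Gsta3 also lost its call without sham replicate 1 (1.07), Clmp without sham replicate 3 (0.457), and Morc4 without any 1 of the 6 arrays (0.697 to 0.793).

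The oxidative stress list, antioxidant and detoxifying enzymes, averaged 0.25 higher at that time, with 19 of 23 members above 0 and 1, Gsta3, called over all genes and adjusted over the list alone (adjusted p = 0.000579, adjusted p = 0.603 with an estimated correlation). Lipogenesis genes averaged 0.55 higher, with 24 of 26 above 0 (adjusted p = 0.000158, adjusted p = 0.603 with an estimated correlation). The fatty acid elongase gene Elovl6 differed by 1.66 ± 0.69 and Acly, which makes cytosolic acetyl-CoA, by 1.40 ± 0.61. With covariates for the mix of tissues both lists lost their calls, at 0.145 (adjusted p = 0.147) for oxidative stress and 0.109 (adjusted p = 0.858) for lipogenesis. T and NK cell genes averaged −1.42 with 0 of 22 above 0 (adjusted p = 2.62e-09), and B cell genes −1.58 with 1 of 22 above 0 (adjusted p = 2.21e-06). Both had an adjusted p of 0.603 with an estimated correlation. Cd3e, a chain of the T cell receptor complex, differed by −2.38 ± 1.21. Without sham replicate 3 these means were −0.637 and −0.746.

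At 4 weeks after 30 cGy Si, proliferation genes averaged 0.85 higher than in sham (3 arrays against 4), with all 22 members above 0. Of these, 0 were called over all genes and 15 were higher adjusted over the list alone (adjusted p = 6.72e-14, adjusted p = 0.79 with an estimated correlation). The cyclin gene Ccna2 differed by 1.33 ± 0.47, the mitotic kinase gene Aurkb by 1.31 ± 0.41, Prc1 by 1.25 ± 0.38 and Cdk1 by 1.23 ± 0.41. Genes of luminal epithelium averaged 0.43 higher, 27 of 28 above 0 (adjusted p = 1.43e-05), and those of basal epithelium 0.42 higher, 20 of 21 above 0 (adjusted p = 5.65e-06). Both had an adjusted p of 0.79 with an estimated correlation, and the basal mean was 0.201 without sham replicate 1. Skeletal muscle genes averaged −1.14 (adjusted p = 1.43e-05, adjusted p = 0.79 with an estimated correlation), −0.504 without sham replicate 3 and −2.07 without sham replicate 1.

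Of single genes at that time, limma called 0, and 1064 had an unadjusted p under 0.05. The smallest p-values belonged to the kinase gene Sgk1 (1.02 ± 0.20), the DNA repair gene Brca2 (0.62 ± 0.13) and Lypd3 (1.21 ± 0.25), all with an adjusted p of 0.132. The centromere gene Cenpm differed by 1.07 ± 0.23 and Tns2, a focal adhesion protein, by −0.46 ± 0.10 (both adjusted p = 0.168). Cdkn1a differed by 0.38 ± 0.29 (adjusted p = 0.745) and Ccng1 by −0.40 ± 0.14 (adjusted p = 0.503). Without the filter on low genes, 4 genes were called.

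At 12 weeks after 30 cGy Si, interferon response genes averaged 0.51 higher than in sham (3 arrays against 3), with 25 of 26 members above 0. Of these, 0 were called over all genes and 6 were higher adjusted over the list alone (adjusted p = 1.3e-15, adjusted p = 0.516 with an estimated correlation). Ifit3 differed by 1.10 ± 0.38, Ifit1 by 0.95 ± 0.31 and the guanylate-binding protein gene Gbp3 by 0.87 ± 0.19. Lipogenesis genes averaged 0.65 higher, 25 of 26 above 0 (adjusted p = 9.08e-12, adjusted p = 0.896 with an estimated correlation). Their mean was 0.367 without sham replicate 2 and 1.01 without sham replicate 3. Oxidative phosphorylation genes averaged 0.20 higher (adjusted p = 9.4e-06, adjusted p = 0.923 with an estimated correlation). The call was lost without Si replicate 3 (0.0740) or sham replicate 2 (0.0274), and the mean was 0.402 without sham replicate 3.

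Single genes at week 12 were led by Gbp3 and the sterol synthesis gene Cyp51 (1.03 ± 0.23), both with an adjusted p of 0.437, followed by Msmo1, of the same pathway (1.02 ± 0.25), and the interferon signal transducer gene Stat2 (0.64 ± 0.16), both with an adjusted p of 0.559. Zfp874b differed by −0.76 ± 0.16 and the cartilage gene Cnmd by −0.89 ± 0.20 (both adjusted p = 0.437). Cdkn1a differed by −0.021 ± 0.31 and Phlda3 by 0.70 ± 0.30 (adjusted p = 0.906). Limma called 0 genes, with 696 at an unadjusted p under 0.05, and 31 without sham replicate 3.

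Over the 3 weeks together (9 Si against 10 sham arrays), 30 cGy Si changed 4 genes, each with the same sign in all 3 weeks. All 4 differed more at week 1 than over the 3 weeks, and Gsta3, Morc4 and Clmp were the genes called at week 1. Limma called 0 genes at week 4 and at week 12. Genes chosen by their mean over 3 weeks tend to share a sign, so the shared sign does not show a lasting change. Gsta3 rose by 0.58 ± 0.11, Morc4 by 0.43 ± 0.075 and Clmp by 0.28 ± 0.054, and Phxr4 fell by 0.56 ± 0.10, all with an adjusted p of 0.0477. The ubiquitin ligase gene Lonrf3 differed by 0.61 ± 0.12 (adjusted p = 0.0516), and Nop53, a ribosome biogenesis factor, by −0.32 ± 0.064 (adjusted p = 0.0647). Cdkn1a was at 0.50 ± 0.18 (adjusted p = 0.222). The 4 calls came from 1939 genes at an unadjusted p under 0.05. Their number depended on single arrays. It was 0 without Si week 1 replicate 1 or 2, sham week 1 replicate 2, any of the Si week 4 replicates, sham week 4 replicate 2 or 4, Si week 12 replicate 1 or 3, or sham week 12 replicate 1 or 2. It was 2 without Si week 12 replicate 2, 7 without sham week 4 replicate 3 and 305 without sham week 12 replicate 3. In these fits with 0 calls, Gsta3 lay between 0.541 and 0.586 and Phxr4 between −0.586 and −0.511. Single calls were also lost without sham week 1 replicate 1 (Gsta3 at 0.560, Phxr4 at −0.547), sham week 1 replicate 3 (Clmp at 0.256), Si week 1 replicate 3 (Phxr4 at −0.545), sham week 4 replicate 1 (Gsta3 at 0.579) and Si week 12 replicate 2 (Clmp at 0.294, Phxr4 at −0.560). Without the filter on low genes, or in a fit of only these groups, 0 genes were called.

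Among lists over the 3 weeks, T and NK cell genes averaged −0.93 with 0 of 22 above 0 (adjusted p = 2.94e-11) and B cell genes −1.01 with 1 of 22 above 0 (adjusted p = 3.45e-08). Cd3g differed by −1.73 ± 0.77 and the B cell gene Ms4a1 by −1.64 ± 0.87. Interferon response genes averaged 0.29 higher, 24 of 26 above 0, with 0 called over all genes and 11 higher adjusted over the list alone (adjusted p = 5.7e-08). Ifit3 differed by 0.72 ± 0.22 and Oasl2 by 0.55 ± 0.17. Lipogenesis genes averaged 0.37 higher, with 3 adjusted over the list alone (adjusted p = 1.02e-05), and oxidative phosphorylation genes 0.15 higher, with 1 (adjusted p = 0.000206). Each of these 5 lists had an adjusted p of 0.802 with an estimated correlation. The oxidative phosphorylation mean over 3 weeks was 0.0891 without sham week 12 replicate 2. With covariates for the mix of tissues it was 0.0505, where the call was lost (adjusted p = 0.384), and the lipogenesis mean was 0.221.

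At 1 week after 10 cGy Si, 11 genes rose against sham (3 arrays against 3) and 0 fell, and 3 groups of stress genes were higher. Heat shock genes, chaperones of misfolded proteins, averaged 0.63 higher with all 16 members above 0, 4 of them called over all genes and 13 adjusted over the list alone. The small heat shock protein gene Hspb1 rose by 1.33 ± 0.19, a 2.51-fold change (adjusted p = 0.0013). Hsph1, an Hsp110 chaperone, rose by 1.66 ± 0.25, a 3.16-fold change (adjusted p = 0.00228), Hspa4l by 0.87 ± 0.16 (adjusted p = 0.0113) and Hsp90aa1 by 0.79 ± 0.15 (adjusted p = 0.0181). The list had an adjusted p of 2.57e-29, and of 0.00157 with an estimated correlation.

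Glucocorticoid response genes averaged 0.53 higher in the same glands, with 19 of 21 above 0, 2 called over all genes and 8 adjusted over the list alone (adjusted p = 2.29e-13, adjusted p = 0.00929 with an estimated correlation). The transcription factor gene Zbtb16 rose by 1.73 ± 0.30 (adjusted p = 0.0106) and Tsc22d3 by 0.89 ± 0.16 (adjusted p = 0.0113), while the co-chaperone gene Fkbp5 differed by 1.12 ± 0.30 (adjusted p = 0.238). Endoplasmic reticulum stress genes averaged 0.30 higher, 16 of 18 above 0, with 0 called over all genes and 9 adjusted over the list alone (adjusted p = 8.08e-11, adjusted p = 0.00796 with an estimated correlation). Hspa5, the main chaperone of that compartment, differed by 0.62 ± 0.17 (adjusted p = 0.27). Other genes that rose were P4ha1, a collagen prolyl hydroxylase (0.84 ± 0.14, adjusted p = 0.0067), Banp (0.79 ± 0.14, adjusted p = 0.0113) and Tinagl1 (0.73 ± 0.13, adjusted p = 0.0106). Cdkn1a differed by 1.09 ± 0.31 (adjusted p = 0.313) and Phlda3 by −0.43 ± 0.30.

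At an unadjusted p under 0.05 there were 712 genes in that comparison. The number of calls was 20 without Si replicate 1, 1 without Si replicate 2, 5 without Si replicate 3, 6 without sham replicate 1 and 3 without sham replicate 2. Hspb1 was called without any 1 of the 6 arrays. The mean of its probe sets gave 0.866. Without Si replicate 2, Hsph1 (1.38, adjusted p = 0.0839) and the other genes named here lost their calls, Zbtb16 at 1.71, Tsc22d3 at 0.862, Hspa4l at 0.605, P4ha1 at 0.649, Banp at 0.645, Hsp90aa1 at 0.630 and Tinagl1 at 0.616. Without Si replicate 3, Zbtb16 was at 1.65, Tsc22d3 at 0.746, Hsp90aa1 at 0.770 and Tinagl1 at 0.737, and none was called. Calls lost without sham replicate 1 were Zbtb16 (1.58), Hspa4l (0.847), Banp (0.690) and Hsp90aa1 (0.749). Those lost without sham replicate 2 were Tsc22d3 (0.80), P4ha1 (0.799), Hspa4l (0.847), Banp (0.755), Hsp90aa1 (0.805) and Tinagl1 (0.726), and without sham replicate 3 Hsp90aa1 (0.805) and Tinagl1 (0.657). A fit of only these 6 arrays called 0 genes and none of the 3 lists with an estimated correlation (adjusted p = 0.65 each). The heat shock list kept its call with an estimated correlation without any 1 of the 6 arrays, at adjusted p-values up to 0.0207, but lost it without the 2 arrays least like the rest (0.643, adjusted p = 0.0523). The glucocorticoid response and endoplasmic reticulum stress lists lost theirs without Si replicate 2 (adjusted p = 0.0567 and 0.0545), without sham replicate 3 (adjusted p = 0.228 and 0.133), with array weights (adjusted p = 0.312 and 0.0871) and without the 2 arrays least like the rest (adjusted p = 0.319 and 0.156).

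**Figure D1:**
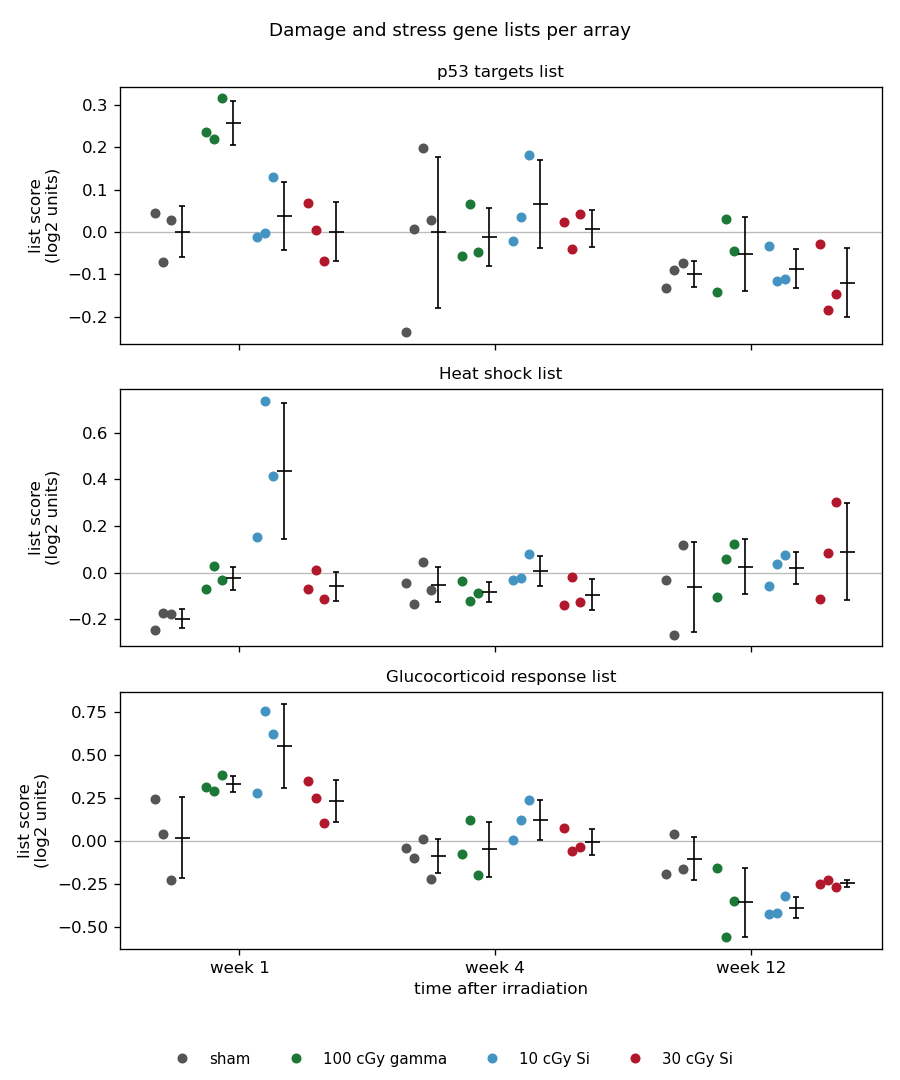
List scores (mean log2 deviation of the members from their means over all 37 arrays, vertical axis) of p53 targets, heat shock and glucocorticoid response genes by week and treatment, with each array as a point and the group mean ± SD. Heat shock and glucocorticoid response scores were higher in the 10 cGy Si glands of week 1, by 0.63 and 0.53 against sham, and p53 target scores in the gamma glands of week 1, by 0.26.

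At 4 weeks after 10 cGy Si, limma called 0 genes (3 arrays against 4), and 418 had an unadjusted p under 0.05. Interferon response genes averaged 0.36 higher, 25 of 26 above 0, with 0 called over all genes and 1 adjusted over the list alone (adjusted p = 2.85e-09, adjusted p = 0.791 with an estimated correlation). Ifit1 differed by 0.79 ± 0.29 and the antiviral gene Mx1 by 0.64 ± 0.26. Macrophage genes averaged 0.30 higher, 25 of 28 above 0 (adjusted p = 9.62e-06, adjusted p = 0.791 with an estimated correlation), led by the scavenger receptor gene Cd163 (0.63 ± 0.23). The macrophage call was lost without Si replicate 1 (0.166, adjusted p = 0.0833), and the mean was 0.192 without sham replicate 1. Of single genes, Fyb2 differed by 0.82 ± 0.18 and Stat2 by 0.58 ± 0.15, and Cdkn1a by 0.52 ± 0.29 (all adjusted p = 1).

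At 12 weeks after 10 cGy Si, glucocorticoid response genes averaged −0.29 against sham (3 arrays against 3), with 5 of 21 above 0, 0 called over all genes and 3 lower adjusted over the list alone (adjusted p = 1.01e-05). Circadian clock genes averaged −0.24, 4 of 17 above 0, with 0 called over all genes and 2 lower adjusted over the list alone (adjusted p = 0.000534). Both had an adjusted p of 0.318 with an estimated correlation. Per1, a member of both lists, differed by −1.18 ± 0.24 and Tsc22d3 by −0.70 ± 0.16 (both adjusted p = 0.507). The clock gene Per2 was at −0.89 ± 0.28, and Arntl, which acts in the opposite phase, at 0.71 ± 0.31 (both adjusted p = 1). Fibroblast genes averaged 0.25 higher, 19 of 21 above 0 (adjusted p = 4.83e-05, adjusted p = 0.992 with an estimated correlation), and 0.153 without sham replicate 1. Limma called 0 genes, with 619 at an unadjusted p under 0.05. Cdkn1a differed by 0.046 ± 0.31.

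Over the 3 weeks together (9 Si against 10 sham arrays), 10 cGy Si left heat shock genes 0.26 higher with all 16 above 0, 0 called over all genes and 12 adjusted over the list alone (adjusted p = 1.24e-14, adjusted p = 0.0673 with an estimated correlation). This mean came mostly from week 1, at 0.63, beside 0.060 at week 4 (adjusted p = 0.613) and 0.081 at week 12 (adjusted p = 0.418). Hsph1 differed by 0.65 ± 0.14 and Hspb1 by 0.50 ± 0.11 (both adjusted p = 0.342). Macrophage genes averaged 0.25 higher, 26 of 28 above 0 (adjusted p = 7.05e-08), and interferon response genes 0.22 higher, 24 of 26 above 0 (adjusted p = 4.12e-07). Both had an adjusted p of 0.565 with an estimated correlation. Cdkn1a was at 0.55 ± 0.18 (adjusted p = 0.569), with the same sign in all 3 weeks, and Frat1 at −0.39 ± 0.087 (adjusted p = 0.342). Limma called 0 genes, with 884 at an unadjusted p under 0.05 and 3 calls without Si week 1 replicate 1.

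Radiation quality was compared as 30 cGy Si against 100 cGy gamma over the 3 weeks (9 arrays against 9), at doses that differ. Oxidative phosphorylation genes averaged 0.24 higher after Si with all 31 above 0, 0 called over all genes and 12 adjusted over the list alone (adjusted p = 3.01e-12). Lipogenesis genes averaged 0.48 higher, 24 of 26 above 0, with 0 called over all genes and 12 adjusted over the list alone (adjusted p = 8.83e-11). Interferon response genes averaged 0.27 higher, 25 of 26 above 0 (adjusted p = 9.38e-09). These 3 lists had an adjusted p of 0.653 with an estimated correlation. Elovl6 differed by 1.04 ± 0.40, Acly by 0.98 ± 0.35 and Sdhd, a subunit of respiratory complex II, by 0.39 ± 0.10. With covariates for the mix of tissues the oxidative phosphorylation mean was 0.0950 and the lipogenesis mean 0.219, both still called at the preset correlation.

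A single gene was called in that comparison: Banp, which encodes a nuclear DNA-binding protein, fell by 0.49 ± 0.083 (adjusted p = 0.0288). Zbtb16 differed by −0.90 ± 0.18, the clock genes Bhlhe40 and Nr1d2 by −0.63 ± 0.13 and −0.42 ± 0.089, and Nr2f1 by 0.30 ± 0.058, with adjusted p-values of 0.0737 or 0.0746. At an unadjusted p under 0.05 there were 1784 genes. Banp was lost and 0 genes were called without gamma week 1 replicate 1 (−0.474) or 3 (−0.491), Si week 1 replicate 1 (−0.474), gamma week 4 replicate 2 (−0.499), Si week 4 replicate 2 or 3 (both −0.493), or Si week 12 replicate 1 (−0.453) or 2 (−0.476). The number of calls was 8 without Si week 4 replicate 1, 5 without Si week 1 replicate 3 and 4 without gamma week 1 replicate 2 or gamma week 12 replicate 3. It was 3 without gamma week 4 replicate 1 or gamma week 12 replicate 2, and 2 without gamma week 4 replicate 3.

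The Si doses were compared in the same way (9 arrays against 9). Zbtb16 fell by 1.09 ± 0.18 with 30 against 10 cGy and Aff1, a transcription elongation factor, by 0.32 ± 0.050 (both adjusted p = 0.00594), and Banp fell by 0.48 ± 0.083 (adjusted p = 0.0148). Zbtb16 and Aff1 were called without any 1 of the 18 arrays. With the mean of its probe sets Aff1 was at −0.264 and not called (adjusted p = 0.24). Banp was not called without Si 30 cGy week 1 replicate 1 (−0.461) or 3 (−0.467), 30 cGy week 12 replicate 1 (−0.440) or 2 (−0.463), 10 cGy week 1 replicate 2 (−0.428), week 4 replicate 2 (−0.458) or week 12 replicate 3 (−0.438), and 8 genes were called without 10 cGy week 1 replicate 1. At an unadjusted p under 0.05 there were 857 genes. Heat shock genes averaged −0.17, 3 of 16 above 0, with 0 called over all genes and 6 lower adjusted over the list alone (adjusted p = 9.28e-08, adjusted p = 0.697 with an estimated correlation). Hsph1 differed by −0.69 ± 0.14 (adjusted p = 0.144). Lipogenesis genes averaged 0.30 higher with 30 cGy in all 26 members (adjusted p = 9.64e-08), and T and NK cell genes −0.72 with 2 of 22 above 0 (adjusted p = 9.28e-08), both with an adjusted p of 0.761 with an estimated correlation. With covariates for the mix of tissues the lipogenesis mean was 0.133.

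Between sham glands of week 4 and week 1 (4 arrays against 3), 254 genes rose and 521 fell. Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, averaged −0.79 with 1 of 22 above 0, 7 lower over all genes and 16 lower adjusted over the list alone (adjusted p = 2.78e-09, adjusted p = 0.334 with an estimated correlation). Fos fell by 2.25 ± 0.45 (adjusted p = 0.00404), Fosb by 2.23 ± 0.49 (adjusted p = 0.00773) and Egr1 by 1.67 ± 0.29 (adjusted p = 0.00161). The phosphatase gene Dusp1 fell by 1.18 ± 0.30 (adjusted p = 0.0165). Notch pathway genes averaged −0.28, with 4 lower over all genes and 7 adjusted over the list alone (adjusted p = 0.002, adjusted p = 0.334 with an estimated correlation). The endothelial receptor gene Notch4 fell by 0.64 ± 0.13 (adjusted p = 0.00541). Foxa1, a transcription factor of luminal cells, fell by 1.16 ± 0.29 (adjusted p = 0.0145) and Pmepa1, a target and inhibitor of TGF-beta signalling, by 1.16 ± 0.25 (adjusted p = 0.00734).

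Among the genes that rose from week 1 to week 4 in sham glands, the eosinophil-associated ribonuclease gene Rnase2a rose by 2.37 ± 0.56, a 5.16-fold change (adjusted p = 0.0129), Cpa3 by 1.27 ± 0.28 (adjusted p = 0.00788), the mast cell protease gene Mcpt4 by 0.98 ± 0.27 (adjusted p = 0.027) and the lectin gene Cd209d by 1.20 ± 0.35 (adjusted p = 0.0401). Macrophage genes averaged 0.39 higher, 25 of 28 above 0, with 3 called over all genes and 3 adjusted over the list alone (adjusted p = 1.9e-05, adjusted p = 0.99 with an estimated correlation). Oxidative phosphorylation genes averaged 0.29 higher, 30 of 31 above 0, with 4 called over all genes and 4 adjusted over the list alone (adjusted p = 1.61e-06, adjusted p = 0.99 with an estimated correlation). Their mean was 0.139 without sham week 4 replicate 1, and 0.122 without the 2 arrays least like the rest, where the call was lost (adjusted p = 0.0883). Mast cell genes averaged 0.31 higher (adjusted p = 0.00841, adjusted p = 0.99 with an estimated correlation), and 0.110 without sham week 1 replicate 3, where the call was lost (adjusted p = 0.0985), as it was with the filter at the 50th percentile (0.237), with array weights (0.181) and without the 2 arrays least like the rest (0.231).

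The 775 calls came from 2721 genes at an unadjusted p under 0.05, and their number was 285 without sham week 1 replicate 1 and 392 without sham week 1 replicate 2. A fit of only these 7 arrays called 0 genes. Fos, Egr1, Pmepa1, Notch4 and Cpa3 were called without any 1 of the 7 arrays, Pmepa1 at −0.735 without sham week 4 replicate 1. Without the 2 arrays least like the rest Cpa3 was at 1.04 and not called (adjusted p = 0.0696). Without sham week 1 replicate 1, calls were lost for Fosb (−1.82), Dusp1 (−0.871), Foxa1 (−1.14), Rnase2a (2.12), Mcpt4 (1.10) and Cd209d (1.28). Without sham week 1 replicate 2 they were lost for Foxa1 (−0.785), Rnase2a (2.26), Mcpt4 (0.936) and Cd209d (0.967). Dusp1 was also lost without sham week 4 replicate 1 (−0.957), Mcpt4 without sham week 1 replicate 3 (0.893), week 4 replicate 1 (0.782) or 3 (0.980), and Cd209d without week 4 replicate 2 (1.15), 3 (1.09) or 4 (1.19). Time, age and place of collection differ together between these weeks and cannot be told apart.

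From week 4 to week 12, sham glands (3 arrays against 4) gave 0 called genes in limma, with 805 at an unadjusted p under 0.05, and 48 without sham week 12 replicate 3. The milk protein gene Ltf, which encodes lactoferrin, differed by 1.55 ± 0.38 (adjusted p = 0.535) and the lipoxygenase gene Alox12e by 2.41 ± 0.57. Rufy3 differed by −0.45 ± 0.084 (adjusted p = 0.117) and Tmem238 by 0.77 ± 0.15 (adjusted p = 0.119). Genes of luminal epithelium averaged 0.34 higher, 23 of 28 above 0, with 0 called over all genes and 4 adjusted over the list alone (adjusted p = 4.59e-05). The call was lost without sham week 12 replicate 1 (0.113) or 2 (0.219), and the mean was 0.687 without replicate 3. Proliferation genes averaged 0.45 higher (adjusted p = 1.3e-05), but 0.0256 without sham week 12 replicate 1 (adjusted p = 0.98) and 0.739 without replicate 2. Skeletal muscle genes averaged −2.07 (adjusted p = 5.97e-12). All 3 lists had an adjusted p of 0.96 with an estimated correlation.

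Whether irradiation effects differed between weeks was tested on the differences of effects. Tsc22d3 was the single gene called in any of the 6 differences: its effect of 10 cGy Si fell by 1.59 ± 0.23 from week 1 to week 12 (adjusted p = 0.00157). It was called without any 1 of the 12 arrays, with adjusted p-values up to 0.0135. The glucocorticoid response list fell with it, by 0.82, with 1 lower over all genes and 12 adjusted over the list alone (adjusted p = 0.00371 with an estimated correlation). That call was lost without sham week 1 replicate 3 (−0.696, adjusted p = 0.0552) and without the 2 arrays least like the rest (adjusted p = 0.109). The effect on heat shock genes fell by 0.57 from week 1 to week 4 (adjusted p = 0.0222 with an estimated correlation) and by 0.55 from week 1 to week 12 (adjusted p = 0.0284). The first of these calls was lost without 10 cGy Si week 1 replicate 2 (−0.422, adjusted p = 0.074), sham week 1 replicate 3 (0.141), 10 cGy Si week 4 replicate 2 (0.0769) or sham week 4 replicate 1 (0.0507), 3 (0.0624) or 4 (0.0617), with array weights (0.223), and without the 2 arrays least like the rest (0.374). The second was lost without 10 cGy Si week 1 replicate 2 (−0.401, adjusted p = 0.0545), sham week 1 replicate 1 (0.0546) or 3 (0.093), 10 cGy Si week 12 replicate 1 (0.0527) or sham week 12 replicate 1 (0.0896) or 3 (0.127), with array weights (0.0562), with covariates for the mix of tissues (0.0546), and without the 2 arrays least like the rest (0.163). The F test over all 6 differences called 0 genes in limma, with 522 at an unadjusted p under 0.05, 2 calls without 10 cGy Si week 1 replicate 1 and 1 without 10 cGy Si week 4 replicate 1.

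The irradiation effects over 3 weeks were compared with each other across 13174 genes, which are not independent replicates. Pearson correlations were 0.603 for the 2 Si doses, 0.513 for gamma and 10 cGy Si, and 0.305 for gamma and 30 cGy Si. All comparisons shared the sham arrays. Unchanged groups were simulated 200 times, with the sham groups simulated too and deviations drawn from the arrays of all groups. Their correlations had means of 0.471, 0.469 and 0.444. Central 95% ranges reached from −0.174 to 0.843, −0.0749 to 0.846 and −0.166 to 0.811. The spread of the real sham arrays, which include the 2 arrays least like the rest, was thus not kept in the simulation. The covariances were 0.0134, 0.00662 and 0.00637 beside simulated values of 0.00875, 0.00871 and 0.00833. With the sham arrays split between the comparisons, 100 times, the correlations averaged 0.0860, −0.162 and −0.0666, with ranges from −0.507 to 0.476, −0.506 to 0.20 and −0.538 to 0.406. Overlaps of calls could not be compared, because gamma and 10 cGy Si had 0 called genes over 3 weeks.

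**Figure D2:**
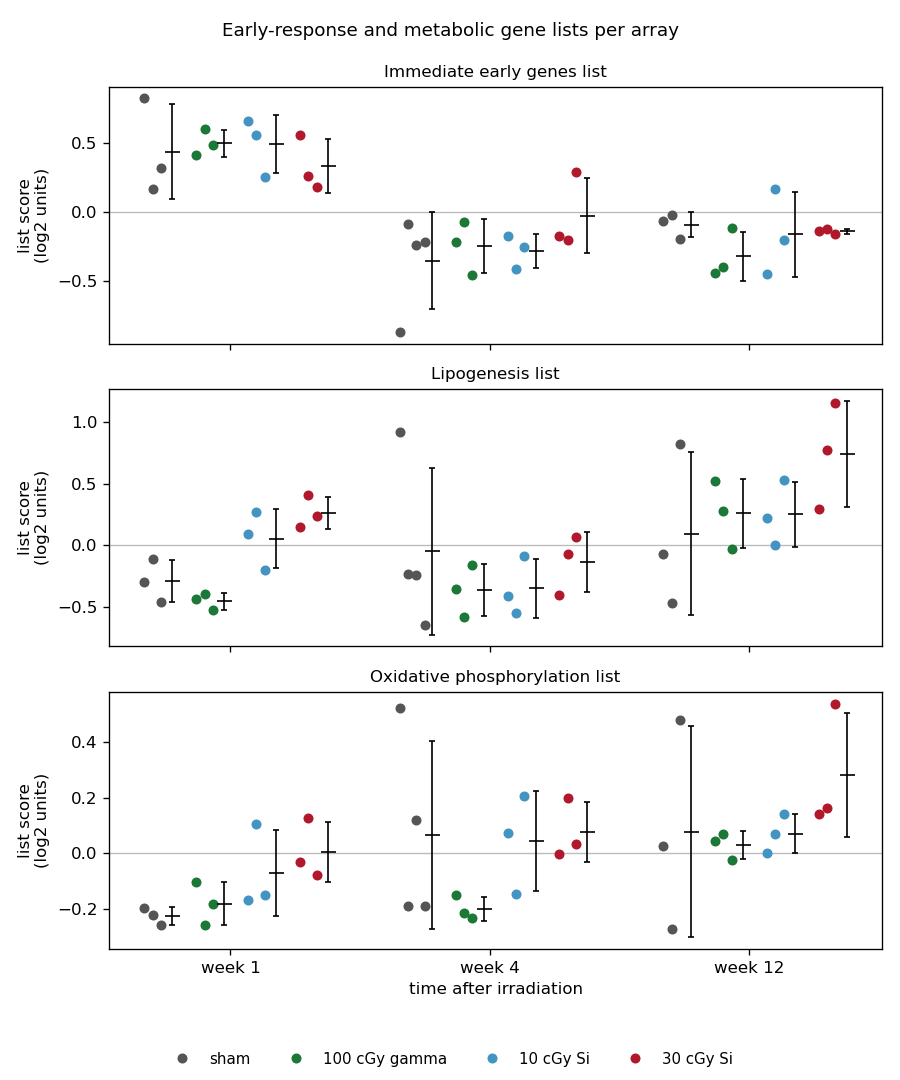
List scores (mean log2 deviation of the members from their means over all 37 arrays, vertical axis) of immediate early, lipogenesis and oxidative phosphorylation genes by week and treatment, with each array as a point and the group mean ± SD. Immediate early scores were lower at week 4 than at week 1, by 0.79 in sham glands.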

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

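The comparison of Si doses, the test without 1 gland, the tests of the glucocorticoid response list alone, the dose test of the lymphocyte lists and the share of genes with the sham direction were chosen after the results they bear on had been seen.

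Heat shock and glucocorticoid response genes were higher than in sham in the 10 cGy Si glands of week 1. The heat shock effect differed from weeks 4 and 12 and the glucocorticoid effect from week 12. The level of the sham arrays bears on this. Heat shock scores of the week 1 sham arrays (−0.244 to −0.172) lay below those of gamma (−0.068 to 0.029) and 30 cGy Si (−0.112 to 0.01) too. Glucocorticoid response scores were −0.227 to 0.242 in sham, 0.292 to 0.383 in gamma and 0.107 to 0.347 in 30 cGy Si. In 10 cGy Si replicates 1, 2 and 3, heat shock scores were 0.154, 0.736 and 0.415, and glucocorticoid response scores 0.279, 0.756 and 0.623. The glucocorticoid response score of replicate 1 thus lay below the gamma arrays and within the range of 30 cGy Si. For heat shock genes, a response that grows with dose, another mix of the tissues behind the 4 covariates and 1 unusual gland are each argued against. The score of 30 cGy minus 10 cGy Si glands was −0.492 (SE 0.106). This SE, like the other SEs of scores below, pools the spread over the 12 groups. The list averaged 0.606 with covariates for the mix of tissues, which do not cover other cell types. It averaged 0.482 without the replicate it leans on most, still called with an estimated correlation (adjusted p = 0.00473). Without the 2 arrays least like the rest it averaged 0.643 and missed the threshold (adjusted p = 0.0523). For glucocorticoid response genes another mix of these tissues is argued against as well, by a mean of 0.541 with the covariates (adjusted p = 0.0147 with an estimated correlation). A response of these genes that grows with dose stays open. Their score difference of −0.318 (SE 0.116) passed the bound of 2 SE, but the array scores of the 10 and 30 cGy groups overlapped. Open too is 1 unusual gland, because the list averaged 0.432 and lost its call without 10 cGy Si replicate 2 (adjusted p = 0.0567). It also lost its call without sham replicate 3 (0.411, adjusted p = 0.228). Stress of the animals around tissue collection would move both lists together in any gland. In the 34 arrays of other groups the deviations of the 2 scores had a Pearson r of −0.222 (permutation p = 0.235). Spearman rho was −0.180 (permutation p = 0.384, 1e+05 permutations each), and r was −0.144 without the 2 arrays farthest from the median. The uncertainty of r is too wide for this test to decide, so such stress stays open. Handling that struck the whole group also stays open, as it cannot be told apart from treatment. So does a stronger response to 10 cGy Si than to the other irradiations, a hypothesis not tested here.

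B cell and T and NK cell genes were lower in 30 cGy Si glands over 3 weeks, by log2 means of −1.01 (SE of the score 0.574) and −0.93 (SE 0.458). Neither list was called with an estimated correlation, and the exact permutation within weeks gave each an adjusted p of 0.362. Lymph node carried along with some glands is a candidate source, because inguinal glands hold a node: of 9 markers fixed for the test 5 were tested, and they averaged −0.447 (SE 0.309), with Ccl19 at −1.74 ± 0.70 and Cxcl13, at a mean level of 8.96, at −1.01 ± 0.54, but the node macrophage gene Siglec1, at 7.63, at 0.21 and Fcna, at 7.27, at 0.50. Stromal cells and macrophages of other tissue may express these markers too, so the value decides neither way. A loss of lymphocytes that grows with dose of Si also stays open: the 10 cGy score lay between sham and 30 cGy Si in 2 of 3 weeks, and 30 minus 10 cGy was −0.72 (SE 0.468).

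Many genes differed between sham glands of week 4 and week 1. Without 1 of the 7 arrays the count fell to 285 at the lowest, short of the bound set beforehand for excluding 1 unusual sham array. Such an array is argued against as the whole cause by direction instead, because 754 of the 775 called genes (97.3%) had the sham direction in the irradiated arrays. A change shared by all treatments had the values it needs: signed by the sham direction, these genes averaged 0.318 (SE 0.025) between weeks 1 and 4 in irradiated arrays, beside 0.530 in sham. Ageing that goes on and the place of collection stay open: the same genes averaged 0.0499 (SE 0.025) from week 4 to week 12 and 0.368 (SE 0.025) from week 1 to week 12, and time, age and place cannot be told apart between weeks 1 and 4.

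In sham glands of week 4, the only group of 4, replicate 1 stood apart from the other 3 arrays in 3 of the 38 list scores: its gap to the nearest array, as a share of the group's range, was 0.887 for TGF-beta signalling, 0.934 for the Wnt pathway and 0.953 for basal epithelium, where chance marks about 1 in 20 groups. Over 38 lists some such marks arise by chance, so this count alone does not set the array apart.

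Several effects differed between weeks by a test of the difference, with an estimated correlation for lists and with limma for the gene. Each of the 6 list calls was lost without the 2 arrays least like the rest, at adjusted p-values from 0.109 to 0.374, while the gene was called there (adjusted p = 0.00516). The 10 cGy Si effect on Tsc22d3 was lower at week 12 than at week 1, by −1.59 ± 0.23 (adjusted p = 0.00157). The 10 cGy Si effect on the glucocorticoid response list differed by −0.819 between those weeks (adjusted p = 0.00371; lost without sham week 1 replicate 3, adjusted p = 0.0552). That on the heat shock list differed by −0.572 between weeks 4 and 1 and by −0.551 between weeks 12 and 1 (adjusted p = 0.0222 and 0.0284), both lost with array weights (0.223 and 0.0562) and the second with covariates for the mix of tissues (0.0546). That on the circadian clock list differed by −0.473 between weeks 12 and 1 (adjusted p = 0.0284), and was lost without 10 cGy Si week 1 replicate 2 (0.0519) or 3 (0.126), sham week 1 replicate 1 (0.0546) or 3 (0.137), 10 cGy Si week 12 replicate 2 (0.0648), or sham week 12 replicate 1 (0.0896), 2 (0.0714) or 3 (0.061), and with the filter at the 50th percentile (0.0985), quantile normalization (0.0681) or the covariates (0.0715). That on the endoplasmic reticulum stress list differed by −0.305 (adjusted p = 0.0444), and was lost without 10 cGy Si week 1 replicate 2 (0.161) or 3 (0.0732), sham week 1 replicate 1 (0.0546) or 3 (0.232), 10 cGy Si week 12 replicate 1 (0.154) or 3 (0.0709), or sham week 12 replicate 1 (0.117) or 3 (0.225), and with the filter at the 50th percentile (0.0985), array weights (0.252) or the covariates (0.0715). The gamma effect on the glucocorticoid response list differed by −0.564 between weeks 12 and 1 (adjusted p = 0.0478), and was lost without any 1 of the 12 arrays except gamma week 1 replicate 2, sham week 1 replicate 1 and gamma week 12 replicate 1, at adjusted p-values from 0.0824 to 0.319, and with no filter (0.0622), the filter at the 50th percentile (0.0586), the mean of probe sets (0.0662), array weights (0.13) or the covariates (0.157).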

How the results depend on the processing

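The fits without the 2 arrays least like the rest, and all tests of the weeks over the 4 treatments, were chosen after the data had been seen. No called gene that is named and no called list that is described reversed its direction under any alternative, and the other calls were not followed one by one, but the numbers of called genes in the irradiation contrasts were small and moved with most settings; the cause was not tested unless given. Fewer samples, and with them fewer degrees of freedom, act in fits of only a contrast's groups, and fewer genes tested in the filter at the 50th percentile. In the fits without 1 array, each call was counted once per array of its contrast left out. Calls of named genes were kept 1572 times and ended 312 times. Calls of the lists described, with the preset correlation, were kept 978 times and ended 39 times. The mean of the probe sets ended 2 calls of named genes and quantile normalization 3, and neither ended the call of a described list with the preset correlation, though the 192 list calls became 186 and 173. Of the 9 list calls with an estimated correlation (3 at week 1 and 6 between weeks), each of these ended 1, no filter 1, the filter at the 50th percentile 3, the block 2, a fit of only the groups compared the 3 of week 1, array weights 6, covariates 4 and leaving out the 2 arrays least like the rest 9. Signal over background was not analysed here.

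With an estimated correlation, 3 of 192 list calls held. With no filter, 4 genes were called for 30 cGy Si at week 4 and 0 over 3 weeks. With the filter at the 50th percentile, 30 cGy Si had 10 calls at week 1 and 11 over 3 weeks, and 7 against gamma. With quantile normalization it had 7 at week 1 and 2 against gamma, and with trend and robust eBayes 5 at week 1 and 7 over 3 weeks. Array weights gave 37 for gamma at week 1, 410 for 30 cGy Si at week 1, 6 at week 4 and 288 over 3 weeks, 88 for 10 cGy Si at week 1, 254 for 30 cGy Si against gamma and 18 against 10 cGy Si, 1557 between sham weeks 4 and 1, and 540 between weeks 12 and 4 over 4 treatments. A fit of only the groups compared gave 0 for gamma, 30 cGy Si and 10 cGy Si at week 1, 0 for 30 cGy Si over 3 weeks and 0 between sham weeks 4 and 1, but 43 for 30 cGy Si against gamma and 99 between weeks 12 and 4; it is the same fit for the interaction. Covariates for the mix of tissues gave 1 for gamma at week 1, 0 for 30 cGy Si at week 1 and 2 over 3 weeks, 4 against gamma and 5 against 10 cGy Si, and 119 list calls, with no value for the lists they are made of. Without the 2 arrays least like the rest, gamma at week 1 had 0, 30 cGy Si had 7 over 3 weeks and 12 against gamma, and weeks 12 and 4 differed in 718. With the sham arrays split, the correlations of effects averaged −0.0666 (gamma and 30 cGy Si) and −0.162 (gamma and 10 cGy Si), both reversed on average, and 0.0860 for the Si doses, with ranges on both sides of 0. The sham arrays were then no longer shared, and each comparison also had fewer of them.

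The replicate number as a block gave 5 for 30 cGy Si at week 1, 0 over 3 weeks, 0 against gamma and 138 between weeks 12 and 4. Same-numbered arrays of a week had a median correlation of deviations of 0.021 over 54 pairs, 21 of them over 0.1, and arrays of different number −0.014 over 117 pairs, 38 over 0.1, so the numbers were not taken to pair the samples. The pairs of week 1 differed by number: over 0.1 were 0 of 6 for replicate 1 (−0.198 to 0.097), 5 of 6 for replicate 2 (0.058 to 0.652) and 6 of 6 for replicate 3 (0.18 to 0.478), which hints at something shared by some arrays. With the block, the 3 list calls of week 1 with an estimated correlation held (heat shock 0.000937, glucocorticoid response 0.0352, endoplasmic reticulum stress 0.00556), but the differences between weeks 12 and 1 were not called for the gamma effect on glucocorticoid response (adjusted p = 0.163) and the 10 cGy Si effect on circadian clock genes (adjusted p = 0.0514).

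Without 1 array at a time, calls ranged from 0 to 5 for gamma at week 1, 0 to 0 at week 4, 0 to 1 at week 12 and 0 to 1 over 3 weeks. They ranged from 0 to 3, 0 to 0, 0 to 31 and 0 to 305 for 30 cGy Si, and from 1 to 20, 0 to 0, 0 to 0 and 0 to 3 for 10 cGy Si. For 30 cGy Si they ranged from 0 to 8 against gamma and from 2 to 8 against 10 cGy Si. Between sham weeks they ranged from 285 to 855 and from 0 to 48, over 4 treatments from 3091 to 3856 and from 109 to 588, and for the interaction from 0 to 2.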

Other observations

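The contrasts between weeks over all 4 treatments and the permutation of list scores were added after the data had been seen. Between week 1 and week 4, over the 12 week 1 and 13 week 4 arrays, 1449 genes rose and 1944 fell. Robo4, a guidance receptor of endothelium, fell by 0.86 ± 0.071 (adjusted p = 1.14e-09), and the endothelial genes Cldn5 and Sox18 by 0.65 ± 0.13 and 0.53 ± 0.073. Endothelium genes averaged −0.21, with 8 of 22 lower over all genes and 9 adjusted over the list alone (adjusted p = 0.000886, adjusted p = 0.618 with an estimated correlation). White adipocyte genes averaged −0.29, with 12 of 25 lower over all genes and 13 adjusted over the list alone (adjusted p = 0.000147, adjusted p = 0.754 with an estimated correlation). Plin1, which coats lipid droplets, fell by 0.56 ± 0.071 (adjusted p = 1.25e-06). Immediate early genes averaged −0.67, with 16 of 22 lower over all genes and 19 adjusted over the list alone (adjusted p = 1.34e-09, adjusted p = 0.498 with an estimated correlation). The lysosomal tetraspanin gene Cd63 rose by 0.82 ± 0.072 (adjusted p = 2.96e-09), Rnase2a by 1.98 ± 0.30 and the milk protein gene Wfdc18 by 1.41 ± 0.25. Interferon response genes averaged 0.22 higher, with 9 of 26 called over all genes and 9 adjusted over the list alone (adjusted p = 0.0022, adjusted p = 0.861 with an estimated correlation), and Ifit3 rose by 0.87 ± 0.19 (adjusted p = 0.000835).

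Between week 4 and week 12, over 13 and 12 arrays, 92 genes rose and 124 fell, a split that became 128 and 92 with quantile normalization. Lipogenesis genes averaged 0.56 higher at week 12 with all 26 above 0, 9 called over all genes and 18 adjusted over the list alone (adjusted p = 1.28e-19, adjusted p = 0.217 with an estimated correlation), and 0.338 with covariates for the mix of tissues. Cyp51 rose by 0.88 ± 0.11 (adjusted p = 0.000117) and Idi1, of the same sterol pathway, by 0.90 ± 0.19 (adjusted p = 0.0115), and Ltf by 0.95 ± 0.20 (adjusted p = 0.011). Glucocorticoid response genes averaged −0.27, with 7 of 21 lower over all genes, and 9 lower and 1 higher adjusted over the list alone (adjusted p = 7.33e-07, adjusted p = 0.217 with an estimated correlation). Tsc22d3 fell by 0.67 ± 0.079 (adjusted p = 3.97e-05), Fkbp5 by 0.88 ± 0.15 (adjusted p = 0.00235), Per1 by 0.66 ± 0.12 (adjusted p = 0.00515) and Zbtb16 by 0.80 ± 0.15 (adjusted p = 0.00673), and each of these genes, with Cyp51, Idi1 and Ltf, was called without any 1 of the arrays. The 216 calls became 126 without gamma week 4 replicate 2, 143 and 137 without 30 cGy Si week 4 replicates 1 and 3, 129 without 10 cGy Si week 4 replicate 1, 588 without sham week 4 replicate 1, 132 without gamma week 12 replicate 2, 109 without 30 cGy Si week 12 replicate 3 and 130 without 10 cGy Si week 12 replicate 3.

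An exact permutation of list scores within weeks asked which of the 38 lists separate treatments over 3 weeks. After adjustment 1 passed: oxidative phosphorylation genes in 30 cGy Si against gamma glands (exact p = 0.00025 over 8000 permutations, adjusted p = 0.0095), higher in each of the 3 weeks. In camera this list was not called there with an estimated correlation, and its mean fell with covariates for the mix of tissues. In the same comparison lipogenesis had an exact p of 0.00325 and the oxidative stress list 0.0045 (both adjusted p = 0.057). Heat shock genes of 10 cGy Si against sham had an exact p of 0.0148 (adjusted p = 0.231, 14000 permutations), and T and NK cell genes of 30 cGy Si against sham an exact p of 0.0519 (adjusted p = 0.362). Smaller exact p-values for 30 cGy Si against sham were 0.0165 for oxidative stress, 0.0231 for endoplasmic reticulum stress and 0.0249 for interferon response (all adjusted p = 0.316).

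Other splits of the same arrays were fitted in the same way. No share is adjusted for the 19 comparisons split in this way, and 1 of 100 is the smallest that 100 splits can give. Unadjusted, shares were under 0.05 for weeks 4 and 1 over 4 treatments (3393 calls, 1 of 100 splits as large, highest other 1280) and for weeks 12 and 4 (216, 1 of 100, highest other 1). Without any 1 array these 2 counts stayed above the highest other split, at 3091 and 109 at the lowest. Both contrasts were added after the data had been seen, so their unadjusted shares do not exclude chance firmly. Shares were also under 0.05 for 30 cGy Si against 10 cGy Si (3 calls, 1 of 100, highest other 0), for the sham difference of weeks 4 and 1 (775 calls, 1 of 35, highest other 712), for 30 cGy Si against gamma (1 call, 3 of 100, highest other 2) and for 30 cGy Si against sham over 3 weeks (4 calls, 4 of 100, highest other 579). These 4 do not exclude chance firmly, as 3 calls are few and became 2 to 8 without 1 array, the sham count fell to 285 without 1 array and to 0 in a fit of only its 7 arrays, and the last 2 counts were 0 in 8 of 18 and 12 of 19 fits without 1 array. Where 0 genes were called, each split has at least as many by construction, which says nothing about chance: gamma and 10 cGy Si over 3 weeks (100 of 100 splits each, highest others 97 and 541), gamma, 30 cGy Si and 10 cGy Si at week 4 (35 of 35 each, highest others 82, 2 and 1), sham weeks 12 and 4 (35 of 35, highest other 645) and the interaction (100 of 100, highest other 1). With 3 arrays against 3 the 10 splits are too few for a share under 0.05: at week 1 gamma had 3 calls (highest other 0), 30 cGy Si 3 (highest other 0) and 10 cGy Si 11 (highest other 34), and at week 12 all had 0 (highest others 28, 72 and 10). Some splits had several times the real count, up to 579 against 4, so groupings other than the treatments can give more calls. The cause was not tested.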
